A study of Mus musculus with 2 samples.

How the data were processed

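Gene expression was measured by microarray in lung cells sorted from mice as SPC/GFP-positive and EpCAM-positive. SPC is the usual abbreviation of surfactant protein C, a product of alveolar type 2 cells, and EpCAM is an epithelial surface protein. One sample came from air-exposed control mice and the other from mice exposed to smoke, each for 3 months. Per the labels, total RNA was extracted with Trizol, checked on a spectrophotometer and a Bioanalyzer, made into biotinylated single-stranded cDNA with a whole-transcript kit and hybridised to Affymetrix Clariom S Mouse arrays. The number of animals behind each sample, their strain and sex, the hour of collection and any pooling are not given in the sources used here.

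The authors deposited 1 value per platform identifier and array, taken here as log2 signal. Each identifier is called a probe here, whether or not it combines several probes of the array. The scale is not stated in the labels and was read from the values, which ran from 1.55 to 19.93 with 2 decimals. Transcriptome Analysis Console is named per the submitters' processing notes, with no version; its settings, the background correction, the normalization between arrays and the genome build are not given in the sources used here. The median was 4.61 on the air array and 4.53 on the smoke array, with quartiles of 3.20 and 7.55 for air and 3.09 and 7.65 for smoke; the levels are close enough that the deposited values look normalized between arrays, which no label states. No detection calls, scanner files or coordinates were used. Both arrays ended at the same highest value, 19.93, shared by 26 probes in air and 25 in smoke; this was read as an upper limit of the deposited scale. The median difference over all probes was -0.02, and it moved with level, from -0.12 to 0.12 across 10 bins of mean level. Scale and centring of the deposited values thus stay unstated, while the direction, smoke minus air, follows from the sample labels. Fold values printed are 2 to the power of the log2 difference and hold on the deposited scale only, because an unknown algorithm can stretch or compress them.

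Of 22206 probes, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2634 are unnamed here. All 19572 gene identifiers matched a RefSeq gene table (assembly GRCm38.p6) by Entrez number, which was used for names only, and 0 symbols changed. They gave 19505 genes, of which 55 had more than 1 probe; their probes were averaged on the log2 scale. The design, the tests, the gene lists, the rule for naming genes and the alternatives, other than those said to be added later, were fixed before the data were examined. With 1 array per group no test across samples was possible, so no p-value is given. A gene was counted as higher or lower when its log2 difference, smoke minus air, was at least 1 or at most -1 (2-fold) and its brighter array was at or above 4.57, the median of all probe values. This filter left 10435 genes. The 16 genes at the upper limit on both arrays have no measurable difference and were left out of counts and lists, which left 10419.

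For 21 gene lists, 11 lists of markers of other cell types and 1 sex-linked list, the median log2 difference of the measured members was set against 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean level. The percentile describes these 2 arrays and is not a p-value. A list was called high at or above the 97.5th percentile and low at or below the 2.5th. Of 731 listed genes, 90 were not in the table and were not analysed here, and 11 stood in more than 1 list. Genes named in the text are the 12 highest and the 12 lowest above the filter, up to 2 members per direction of each list past 2-fold (or, where none was, the member above the filter with the largest difference), and 18 fixed in advance, of which Xist and Ddx3y were not analysed here. Further list members named in the text were chosen after their values were seen.

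The precision of a single gene was described by the spread of differences among genes of like level. Its robust SD, a scaled median absolute deviation, ran from 0.30 to 0.50 across 10 bins of mean level and was 0.30 in the lowest bin and 0.39 in the highest. This spread holds both measurement error and real differences, and it does not replace replicates. The procedure was tested on simulated data made from the air array with this spread, added to each gene independently. Lists whose genes vary together were not simulated, so the result for unshifted lists does not cover them. Over 19505 genes, 87.0% of genes changed 2.83-fold and 96.0% of genes changed 8-fold were recovered, 342 of 9972 unchanged genes above the filter also passed 2-fold, a list of 20 genes shifted by 0.7 reached the 100th percentile, and 8 of 200 unshifted lists fell outside the central 95%.

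Alternatives comprised no filter, a filter at the 75th percentile or on the mean of both arrays, thresholds of 1.5-fold and 3-fold, quantile normalization, centring on the overall median or on a running median over 501 genes ordered by level, an offset of 16 on the linear scale, the brightest probe per gene, list members above the filter only, and list means. A 4-fold threshold and lists with upper-limit genes kept at 0 were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.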

Results

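Sorted lung cells positive for the SPC/GFP reporter and for EpCAM were profiled after 3 months of smoke exposure and compared with the same sorted population from air-exposed control mice. Each condition was represented by 1 Clariom S Mouse array, a whole-transcript array, with 1 deposited signal per platform identifier, called a probe here. The number of arrays therefore limits the precision: no difference has a replicate check, an SD or a p-value, and each compares these 2 samples, not the conditions. Across 22206 probes the arrays correlated with Pearson's r = 0.989 and Spearman's rho = 0.971, which are correlations across probes and not across samples. The SD of the probe differences was 0.50 on the log2 scale.

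The comparison of smoke with air asked which genes of the sorted cells differed after 3 months of exposure. The smoke array had higher signals of Dbp, Cfb, Nr1d1, Vnn1 and Pigr and of inflammatory cytokines and NF-kB targets. It had lower signals of Retnla, Npas2 and Arntl and of endothelial and alveolar type 1 markers, while the measurable alveolar type 2 genes had a median log2 difference of 0.05 and a mean of 0.22. Of 10419 genes above the level filter, 410 were at least 2-fold higher and 258 at least 2-fold lower in the smoke array. At 4-fold the counts were 32 higher and 13 lower, and at 8-fold they were 7 and 4. A normal distribution with the spread of genes of like level would put 220 genes past 2-fold on the higher side and 140 on the lower side. Past 4-fold it would put 0.21 and 0.15 genes. The spread was taken from these same differences, and noise need not be normal in its tails. Without replicates, the excess over these counts does not separate noise from real differences.

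Dbp, a D-box transcription factor driven by the circadian clock, had the largest difference, with a log2 signal of 8.05 in air and 16.48 in smoke, a log2 difference of 8.43. Cfb, complement factor B, was 25.6-fold higher (5.15 in air, 9.83 in smoke). Nr1d1 and Nr1d2, the REV-ERB nuclear receptors that repress transcription in the clock, were 20.4-fold and 7.26-fold higher, and Per3, a period-family clock gene, was 5.82-fold higher. Vnn1, the pantetheinase vanin 1, was 17.5-fold higher (9.21 and 13.34). Ly6i, of the Ly6 family of surface proteins, was 11.7-fold higher, and the metalloreductase gene Steap4 was 9.99-fold higher. Pigr, the receptor that carries polymeric immunoglobulin across epithelium, stood at 14.04 and 17.22, 9.06-fold higher. Tnfrsf9 (the receptor 4-1BB), St6galnac3 (a sialyltransferase) and Csf1 (the macrophage growth factor M-CSF) were 6.54-fold, 6.06-fold and 5.66-fold higher; St6galnac3 was below the filter in air (4.22), and its log2 difference of 2.60 was 1.90 with an offset of 16 on the linear scale. The robust SD of differences among genes of like level was 0.39 to 0.50 for these 12 genes.

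Retnla, a secreted resistin-like protein induced in type 2 immune responses, had the largest difference on the lower side, at 12.36 in air and 7.07 in smoke, 39.1-fold lower. Npas2 and Arntl (BMAL1), which activate transcription in the clock, were 14.8-fold and 12.3-fold lower, and Nfil3, a repressor that acts on the same D-box elements as Dbp, was 4.06-fold lower. Ccnjl, a cyclin J-like gene, was 10.6-fold lower. Clca1, a secreted goblet cell protein, and Avpr1a, a vasopressin receptor, were at 6.13 and 6.85 in air and below the filter in smoke, at 3.22 and 4.32. Their log2 differences of -2.91 and -2.53 were -1.76 and -1.87 with the offset, so their size depends on how low signals are treated. Rasl11a, a small GTPase gene, stood at 14.37 in air and 11.96 in smoke, 5.31-fold lower, and Klhl13, a ubiquitin ligase adaptor, was 5.17-fold lower. The remaining genes of the 12, Olfr1188, Defb5 and Zfp709, had signals of 4.98, 5.77 and 5.31 in air and under 3.5 in smoke, close to the level filter of 4.57, and their log2 differences of -2.44, -2.44 and -2.06 were -1.12, -1.44 and -1.13 with the offset.

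**Figure D1:**
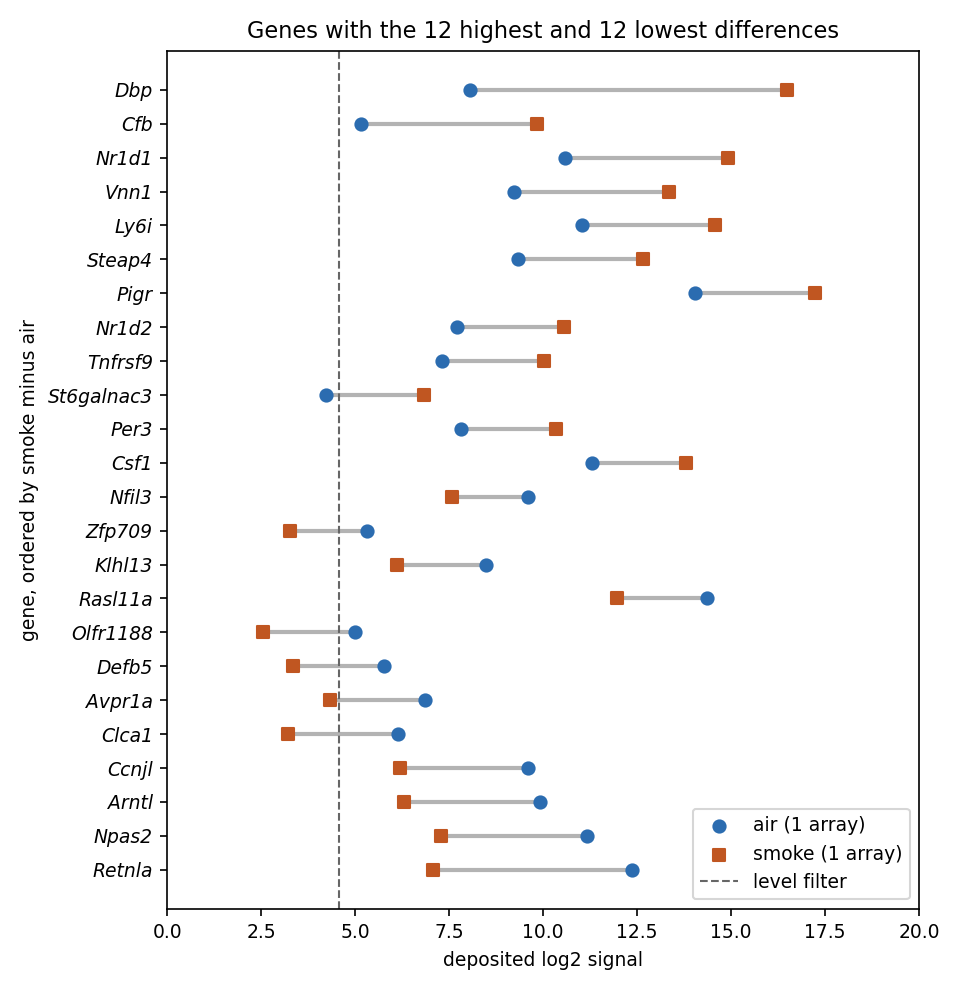
Deposited log2 signal (horizontal axis) of the genes with the 12 highest and 12 lowest differences above the level filter, ordered from bottom to top by smoke minus air; circles are the air array, squares the smoke array, 1 array each, and the dashed line is the level filter at 4.57. Dbp lies at 8.05 in air and 16.48 in smoke, and Retnla at 12.36 and 7.07.

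The identity of the sorted cells was examined with surfactant and other alveolar type 2 genes. Sftpc, the gene of the sorting reporter, stood at the upper limit of 19.93 on both arrays, as did Sftpb, Sftpa1, Lamp3, Slc34a2, Muc1, Cxcl15 and Lyz2, so no difference could be measured for these 8 genes. The 20 other type 2 genes had a median log2 difference of 0.05, at the 56.3rd percentile of random lists, and a mean of 0.22, at the 91.2nd; 14 were higher and 5 lower. Among the 20, Etv5 (19.91 on both arrays) and Napsa (19.61 in air and 19.76 in smoke) lay just under the limit, where a rise could hardly show. Abca3, the lamellar body lipid transporter, was at 18.76 in air and 18.80 in smoke. Chil1, a chitinase-like secreted protein, was the 1 member past 2-fold, at 17.34 in air and 19.66 in smoke, 4.99-fold higher. Epcam, the second sorting marker, was at 11.09 and 10.92, and the 22 measured junction and adhesion genes had a median of 0.05, with 0 past 2-fold; the largest of these differences was that of the desmosomal cadherin Dsg2, at -0.92.

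Inflammatory cytokines and NF-kB targets had the largest median difference among the lists fixed in advance. The 27 measured members had a median log2 difference of 0.68, higher than all of the 10000 random lists, whose central 95% ran from -0.18 to 0.23. Of 21 members above the filter, 11 were at least 2-fold higher, 1 at least 2-fold lower and 9 within 2-fold. Csf1 was 5.66-fold higher, and Saa3, an acute phase protein of epithelium and macrophages, was 5.28-fold higher (5.09 and 7.49). Csf2 (GM-CSF), the neutrophil-attracting chemokines Cxcl5, Cxcl2 and Cxcl1, and the NF-kB feedback inhibitors Tnfaip3 and Nfkbia had log2 differences of 2.29, 2.03, 1.97, 1.79, 1.88 and 1.43. Csf2 was below the filter in air, at 4.42. Above the filter 18 members were higher and 3 lower, which were Ccl2 (-0.57), Ccl20 (-0.48) and Il18. Bcl3 and Nfkbiz differed by 0.01 and 0.03. Il18 was at 4.69 in air and 3.38 in smoke, a log2 difference of -1.31 that was -0.66 with the offset. Lcn2, a secreted siderophore-binding protein, was at the upper limit on both arrays. Neutrophil markers, measured in the same arrays, had a median of 0.24 at the 97.8th percentile, with Il1r2 the 1 of 7 members above the filter past 2-fold (a log2 difference of 1.12 from 4.49, and 0.75 with the offset); this list left the top 2.5% under quantile normalization (96.7th percentile) and under centring by level (97.4th), and the median of its 7 members above the filter was 0.60, at the 98.9th, with Il1r2 and Retnlg among the 7 by their smoke signals alone (4.49 and 4.25 in air). The neutrophil list had a mean of 0.33, at the 99.7th percentile, and a median of 0.13 with the offset, at the 98.6th. S100a8 and S100a9, the abundant granulocyte calcium-binding proteins, differed by 0.28 and -0.19.

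Interferon-stimulated genes had a median of 0.14 over 26 measured members, at the 97.2nd percentile, just inside the central 95%. Only 11 of them were above the filter; of these, Irf7, a transcription factor of the interferon response, was 2.69-fold higher and Rtp4 was 2.07-fold higher, and 9 were within 2-fold. With the offset the log2 differences of Irf7 and Rtp4 were 0.91 and 0.76, under 2-fold. Among those above the filter the median was 0.69, at the 100th percentile of random lists drawn above the filter. Irf7 and Usp18 were among these by their smoke signals alone (4.11 and 4.46 in air), and Gbp3 by its air signal alone (4.36 in smoke). Over all 26 members, 16 were higher and 9 lower. Genes of MHC class II presentation had a median of 0.26 at the 88.0th percentile, and H2-DMb2, a subunit of the peptide-loading chaperone, was the 1 of 7 members past 2-fold, 2.30-fold higher.

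Aryl hydrocarbon receptor targets, which respond to polycyclic hydrocarbons of smoke, had a median of -0.03 and a mean of 0.24 over 9 members (47.8th percentile of medians, 95.2nd of means). Cyp1a1, the most widely used target, was below the filter on both arrays, at 2.79 in air and 2.53 in smoke. Cyp1b1 was at 3.39 in air, below the filter, and 5.06 in smoke, just above it, a log2 difference of 1.67 that was 0.90 with the offset. Nqo1 was also below the filter, at 3.34 and 4.04. Among the 5 members above the filter, 3 were higher and 2 lower. Tiparp was at 7.67 in air and 8.55 in smoke, a log2 difference of 0.88. The NRF2 and glutathione list had a median of 0.08 over 31 members (66.7th percentile). Of 27 above the filter, Sod2, the mitochondrial superoxide dismutase, was 2.17-fold higher, Gpx3, a secreted glutathione peroxidase, was 2.22-fold lower, and the other 25 were within 2-fold.

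Fatty acid and phospholipid synthesis genes had a median of 0.28 over 21 members, at the 98.8th percentile, with 0 past 2-fold; Fads1, a fatty acid desaturase, had the largest difference, 0.85, and Scd1 and Elovl1 were at the upper limit on both arrays. The list lay inside the central 95% as a mean (0.22, 93.8th percentile), with the offset (0.19, 96.5th) and over members above the filter (0.29, 97.4th). Cholesterol synthesis genes had a median of -0.04 and a mean of 0.02 (15.8th percentile of medians), with the sterol dehydrogenase Nsdhl 2.27-fold higher. Subunits of oxidative phosphorylation (median 0.12, 72.4th percentile, 0 of 41 past 2-fold, largest difference Ndufb6 at 0.93) and cytosolic ribosomal proteins (0.11, 68.9th percentile, 0 of 34, largest difference Rplp0 at 0.80) lay inside the central 95%. Autophagy and lysosome genes had a median of 0.18 (78.6th percentile); Atg7, the enzyme that activates the autophagy conjugation system, was 2.40-fold higher, and 23 of 24 members above the filter were within 2-fold. Genes of the unfolded protein response had a median of 0.20 (90.2nd percentile), with Herpud1, a component of endoplasmic reticulum-associated degradation, 2.16-fold higher and the other 23 above the filter within 2-fold. Under quantile normalization the medians of the oxidative phosphorylation, autophagy and unfolded protein response lists were 0.02, 0.07 and 0.08. Those of the ribosomal and cholesterol lists were 0.05 and -0.145.

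Heat shock genes went in both directions. Hspa1a and Hspa1b, the inducible HSP70 genes, which are near-identical copies that probes may not separate, were 3.76-fold and 2.89-fold higher, and Hsph1 was 2.01-fold lower; the list's median was -0.05 and its mean 0.22. Immediate early genes, which respond to tissue dissociation, had a median of -0.09 at the 7.8th percentile. Junb was 2.11-fold higher and Fosb 2.25-fold lower, and the other 21 were within 2-fold.

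Proliferation genes had a median of -0.21 over 28 members, at the 4.9th percentile. The median of the 17 members above the filter was -0.11, at the 22.7th percentile, and the mean over the 28 was -0.13, at the 12.3rd. Mki67, the Ki-67 proliferation antigen, was at 7.32 in air and 6.65 in smoke, and Aurka, a mitotic kinase, had the largest difference above the filter, -0.93; 0 of 17 members above the filter passed 2-fold. For p53 targets and senescence genes the median was 0.02 at the 57.6th percentile, with 0 of 14 past 2-fold. Cdkn1a, the p21 cell cycle inhibitor, was at 12.23 and 11.53, Cdkn2a was below the filter at 2.04 and 1.84, and Fas, a death receptor, had the largest difference, 0.99. Wnt targets (median -0.06, 43.0th percentile, 0 of 8 past 2-fold, largest difference Notum at -0.94) and Notch pathway genes (median -0.16, 12.3rd percentile, Dll1 2.08-fold lower from 5.39) lay inside the central 95%.

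Markers of alveolar type 1 cells, the flat gas-exchange cells that type 2 cells can replace, had a median of -0.28 over 19 members, at the 0.2nd percentile. No member passed 2-fold, and 15 of the 19 were lower; Clic5, a chloride channel family gene, had the largest difference, -0.68. Hopx was at 8.70 in air and 8.42 in smoke. Ager, the most used type 1 marker, was at 18.41 in air and 18.54 in smoke, a difference of 0.13. The transitional epithelial list had a median of -0.17 at the 2.6th percentile; Krt8, the keratin that defines that state, was 2.16-fold lower (10.50 and 9.39), and the other 18 members above the filter were within 2-fold. Under the mean over members this list lay at the 0.7th percentile. Mesenchymal transition regulators had a median of -0.25 at the 0.9th percentile, although Tgfb1, a profibrotic cytokine, was 2.40-fold higher while Tgfbi, an extracellular matrix gene, was 2.07-fold lower; under quantile normalization the list lay at the 2.53rd percentile, out of the lowest 2.5%. Endothelial markers, which lie outside the sort, were lower in the same array (median -0.41).

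Markers of cell types outside the sort were read as levels of the whole sample. Endothelial markers had a median of -0.41 over 19 members at the 0.01st percentile, and 13 of 17 members above the filter were lower. Cldn5, an endothelial tight junction gene, and Eng, endoglin, were 2.25-fold and 2.04-fold lower, and Pecam1 was at 10.70 in air and 9.97 in smoke. Macrophage and monocyte markers had a median of -0.16 (11.1th percentile), with Chil3, a chitinase-like macrophage protein, 2.64-fold lower. Lymphocyte markers had a median of 0.02 (74.1st percentile); Ptprc, the pan-leukocyte gene CD45, was at 7.64 and 7.59, and Cd3d was 2.04-fold higher from below the filter. Fibroblast and smooth muscle markers had a median of -0.12 (19.7th percentile), with Col1a1 2.27-fold lower, Pdgfrb at 6.09 in air and 5.09 in smoke, and Col6a1 2.22-fold higher. Among airway cells, Scgb1a1, the club cell secretoglobin, was at the upper limit on both arrays, and Scgb3a1 was 3.56-fold lower (6.85 and 5.02); the club and secretory list had a median of -0.07 (32.7th percentile). Ciliated markers had a median of -0.18 (14.2nd percentile), with Tppp3 2.71-fold lower and Cfap126 2.95-fold higher. Basal and neuroendocrine markers (-0.05, 56.4th percentile, with the synaptic vesicle gene Syp, the 1 member above the filter, at -0.43), mesothelial markers (0.02 with a mean of -0.08, 67.3rd percentile, Msln 2.43-fold lower) and erythroid and platelet markers (-0.43, 4.7th percentile, with a mean of -0.18 at the 25.5th percentile, Pf4 2.14-fold higher) lay inside the central 95%. All 5 measured sex-linked genes, which are on the Y chromosome, were below the filter on both arrays.

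**Figure D2:**
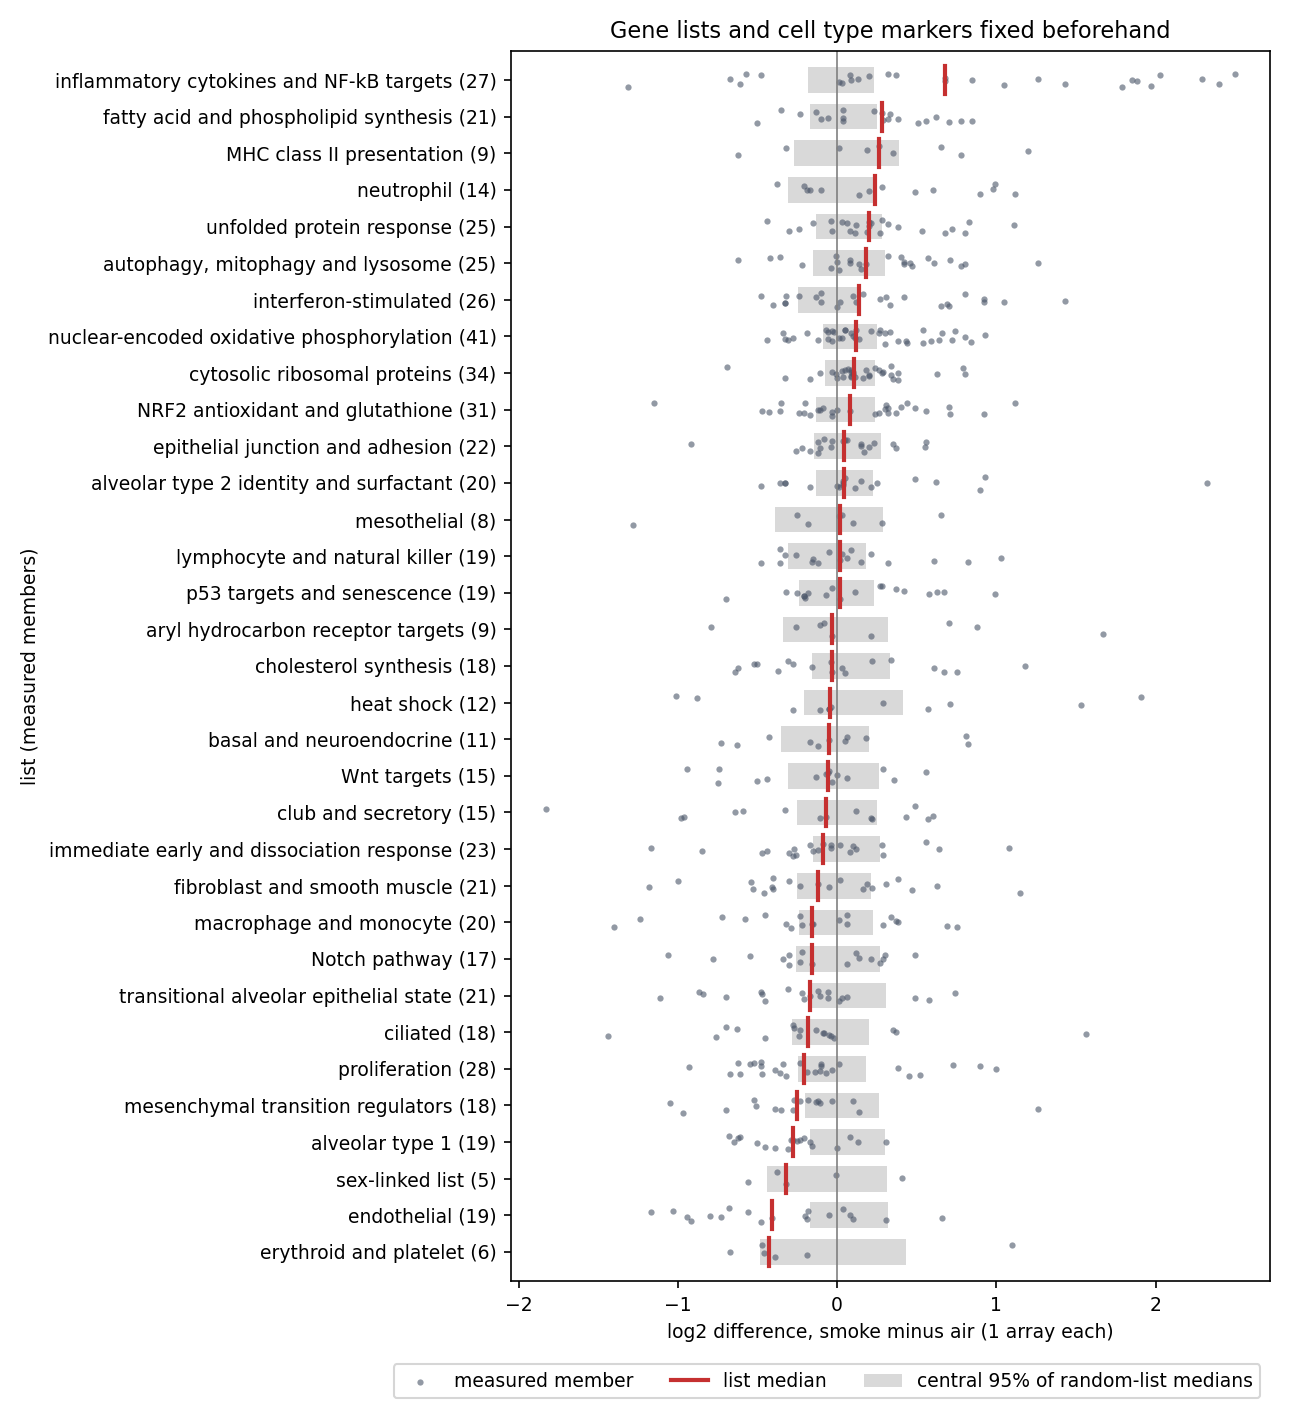
Log2 difference, smoke minus air, of the measured members of each list (points), with the list median (red line) and the central 95% of medians of 10000 random lists matched on level (grey bar); the number of measured members is in parentheses and each condition is 1 array. Inflammatory genes lie highest relative to their bar (median 0.68), and the endothelial median of -0.41 lies below its bar.

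Across the 33 lists, 3 lay at or above the 97.5th percentile (inflammatory, fatty acid and phospholipid synthesis, neutrophil) and 3 at or below the 2.5th (endothelial, alveolar type 1, mesenchymal transition). Lists of unrelated genes would put 1.65 of 33 outside the central 95%. Genes of 1 list can vary together between 2 samples, so this figure is no measure of chance here. The fatty acid, neutrophil and mesenchymal lists lay inside the central 95% under at least 1 alternative. The inflammatory, endothelial and alveolar type 1 lists lay outside it in all 7 settings run. Some of these settings could change little. All 19 measured type 1 members were above the filter, and neither the type 1 nor the endothelial list had upper-limit genes. The brightest-probe setting could affect only genes with more than 1 probe. The medians of the junction, Wnt, club and basal lists turned sign under quantile normalization and centring by level, and that of the lymphocyte list under quantile normalization. Over members above the filter only, the medians of the aryl hydrocarbon receptor (0.21), NRF2 (-0.03), Notch (0.09) and fibroblast (0.02) lists had the opposite sign. Of the genes named as past 2-fold, Hsph1, Tgfbi, Dll1, Cd3d, Col1a1, Pdgfrb, Pf4 and Msln were also under 2-fold with the offset, and Herpud1 and Junb under quantile normalization.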

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

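With 1 array per group no replicate could be left out. No paired analysis was possible because each group holds 1 sample. The 4-fold setting and the lists with upper-limit genes at 0 were chosen after the data were seen. Against 410 genes higher and 258 lower, the counts were 212 and 74 with the filter at the 75th percentile, 1514 and 958 at 1.5-fold, 66 and 35 at 3-fold, 32 and 13 at 4-fold, and 243 and 102 with the offset of 16; with no filter 407 genes were lower. Quantile normalization, the 2 centrings, the filter on the mean of both arrays and the brightest probe gave both counts within 1.5 times those. Pearson's r was 0.982 among probes above the filter. Among the 78 named genes with a difference, none past 2-fold turned sign under the 4 settings run on them, while under quantile normalization Abca3 (0.04 to -0.02) and Ager (0.13 to -0.01), both within 2-fold, did. Each of the 78 had 1 probe, so the brightest-probe setting could not change them. With the offset, which by construction shrinks differences at low signal, 13 were under 2-fold: Cyp1b1, Il18, Irf7, Rtp4, Hsph1, Tgfbi, Dll1, Il1r2, Cd3d, Col1a1, Pdgfrb, Pf4 and Msln. Under quantile normalization 2 were, Herpud1 and Junb. In all 7 settings run, some of which left list members unchanged, the inflammatory, endothelial and alveolar type 1 lists stayed outside the central 95%. The fatty acid list fell inside it with the offset (median 0.19), above the filter only (0.29) and as a mean (0.22). So did the mesenchymal list under quantile normalization (-0.22) and the neutrophil list under quantile normalization (0.27) and centring by level (0.28). Lists that passed only under an alternative were the transitional list (-0.23 after centring by level, -0.15 with the offset, -0.17 above the filter, -0.20 as a mean), interferon (0.24 quantile, 0.25 centring, 0.69 above the filter, 0.25 as a mean), proliferation (-0.21 quantile, but -0.11 above the filter and -0.13 as a mean), club (-0.33 above the filter), and erythroid and platelet (-0.46 quantile, -0.43 centring, -0.29 offset, but -0.18 as a mean). The type 2 mean was 0.22, at the 91.2nd percentile, and above the filter the p53, ciliated and basal medians were 0.28, -0.43 and -0.43. For the changes of lists the cause was not tested. The upper limit of 19.93 hides any difference of the 16 genes at it.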

Other observations

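The tests of explanations given here, and the lists of acute phase, NADPH oxidase 1, type 2 response, glucocorticoid-induced and clock genes, were chosen after the result was seen, so they are not independent evidence. Acute phase and complement genes, many of them made by epithelium in inflammation, were listed with Cfb and Saa3 among them. Of 24 measured members 16 were higher, and of 16 above the filter 10 were at least 2-fold higher and 0 lower, with a median of 0.50. Without Cfb, the 1 member among the 24 largest differences, the median was 0.48. Kng2 (kininogen 2), Saa4, C1ra, Orm1, Orm2, Itih4 and Lrg1 had log2 differences of 2.38, 2.27, 2.13, 1.76, 1.67, 1.49 and 1.36 (Saa4 and Orm2 from signals below the filter in air, 3.02 and 4.53), whereas 8 members were lower, among them Cfi (-0.48), Saa1 (-0.39) and Serpina3n (-0.18). Noxo1, Noxa1 and Cyba, subunits of the NADPH oxidase 1 complex that makes superoxide, differed by 2.22, 2.16 and 1.04; Noxa1 was below the filter in air, at 2.94, so that the size of its difference is uncertain, and the catalytic gene Nox1 was below it on both arrays, at 2.23 and 2.58.

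Beside Retnla and Clca1, 2 other genes of type 2 responses were more than 2-fold lower, Arg1 (-1.47, to a signal of 3.14, below the filter) and Chil3 (-1.40). The 13 genes of that group as a whole had a median of -0.21 at the 10.99th percentile, and the 11 outside the 24 largest differences had a median of -0.11 at the 31.3rd, both inside the central 95%. The 6 glucocorticoid-induced genes had a median of 0.43 at the 95.1st percentile, with Per1, also a clock gene, the 1 member past 2-fold. Among 1190 unnamed probes above the filter, 52 were at least 2-fold higher and 57 lower, with differences from -3.45 to 6.45.

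The pattern with the largest differences was among circadian clock genes, which made up 7 of the 24 genes named by size, 4 higher and 3 lower. The repressors and outputs of one phase (Dbp, Nr1d1, Nr1d2, Per1, Per2, Per3, Ciart, Bhlhe41 and others) were higher in 12 of 12 cases, 10 of them above the filter and 8 of these past 2-fold, with Hlf (0.07) and Usp2 (0.58) below the filter. Ciart, Bhlhe41 and Tef passed it by their smoke signals alone (2.87, 4.01 and 3.92 in air). The activators and genes of the opposite phase (Arntl, Npas2, Clock, Nfil3, Cry1) were lower in 5 of 5, 4 of them past 2-fold. The gap between the 2 medians was 4.09 on the log2 scale. A trend with signal level is argued against by its size. The median difference ran only from -0.12 to 0.12 across bins of level, and the gap was 4.18 after centring by level. The 10 clock genes outside the 24 had a signed median of 1.10, at the 100th percentile of random lists, but they were listed after their values were seen, so this does not decide whether the grouping arose by chance. A different hour of collection is a candidate explanation, as is a change of clock phase with smoke exposure. The gap of 4.09 prompted both explanations, so it tests neither. With 1 sample per condition and the hour not given in the sources used here, they cannot be told apart.

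The higher inflammatory and NF-kB list stayed at the 100th percentile after centring by level (median 0.55), which argues against a trend with signal level. Neutrophils carried into the smoke sort would bring S100a8 and S100a9, whose mean difference was 0.045, below the 2-fold that 11 list members passed. The spread of this mean was 0.34 if the 2 genes vary independently. On these 2 genes alone, this argues against neutrophils as the whole source. The 7 neutrophil genes above the filter had a median of 0.60. Of these 5 were higher, Il1r2 and Retnlg among them from signals below the filter in air, and S100a9 and Wfdc21 were lower. This does not exclude neutrophils for a part of the difference. A stronger response to dissociation could raise many of the same genes; the immediate early list lay at the 7.8th percentile (7.82), which neither requires nor excludes it, because the time courses of the 2 groups of genes can differ. Smoke exposure, the difference the design names, stays open and untested, as does the hour of collection.

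Lower endothelial and alveolar type 1 markers also held after centring by level, with medians of -0.52 and -0.33 and neither list above the 0.28th percentile, which argues against a trend with signal level. Fewer endothelial cells carried into the smoke sort may account for the endothelial part, although the EpCAM gate should remove such cells. Whether such cells, or a different share of type 1 cells in the sort, contributed to the type 1 difference was not tested. Fewer carried-over cells would lower their markers alike if no other cells in the sample made them and signals lay above background. Neither condition was tested. The robust SD of the 17 members above the filter about their median was 1.39 times that of single genes of like level (0.64 against 0.46). Vwf, Plvap and Esam were at 0.04, 0.31 and 0.66, and Cdh5 and Eng at -0.48 and -1.03. These values do not decide whether fewer endothelial cells were carried over. A lower expression of these genes in the sorted cells after smoke exposure was not tested.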
